A study of Danio rerio with 18 samples.

How the data were processed

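Gene expression was measured in pools of whole zebrafish embryos at 24 hours post fertilisation (hpf) on NimbleGen single-colour arrays, 18 arrays in all. In the 0.1 µM experiment, embryos were exposed from 8 to 24 hpf to solvent, bisphenol A (BPA), 17β-estradiol (E2) or GSK4716, with 3 arrays per group (12 arrays). In the high-concentration experiment, embryos were exposed to solvent, 80 µM BPA or 15 µM E2, with 2 arrays per group (6 arrays). For the 0.1 µM experiment the series text states biological replicates and 40 embryos pooled per replicate; for the high-concentration experiment nothing used here states whether the replicates are independent. The p-values therefore measure only the spread between arrays.

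The deposited value per target is an RMA intensity on a linear scale, which the authors background corrected, quantile normalised between arrays and summarised over the probes of each target. The version of the RMA software is not given in the sources used here. Each array held 38489 targets, of which 36632 had 3 probes, 1796 had 2 and 61 had 1. The files hold no detection calls, so signal near background could not be set apart by a call. The deposited value tables of both experiments equalled the array files for all targets. The experiments have different platform records and were normalised as separate sets with different RNA extraction reagents, so no test was made across them. The log2 was taken of each intensity.

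Targets were named from a RefSeq accession where one matched (2663 of 3055 targets with one), otherwise from the symbol in the files where it matched a current symbol (12189 targets). An unmatched file symbol was kept for 6412 targets, and 17225 targets had no symbol. This gave 10958 different current symbols. Positions are those of the files, whose scaffold names are those of assembly Zv7. vtg1, esr2b and cyp1a were not measured under a name.

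Each experiment was fitted in 1 model with limma 3.58.1 in R 4.3.3 (group means, lmFit, contrasts, eBayes), with two-sided tests and Benjamini-Hochberg adjustment over all 38489 targets; a target was called at an adjusted p under 0.05. SE and 95% intervals are limma's. In simulated data of the size of the 0.1 µM experiment, this test recovered 69.9% of targets changed 1.5-fold and 91% of those changed 2-fold, with 11 false calls per simulation. In simulated data of the size of the high-concentration experiment it recovered 0% and 19.1% of these and 61.5% of targets changed 4-fold, with 1.4 false calls per simulation. The number of arrays limits the precision: the median 95% interval was ± 0.177 log2 in the 0.1 µM experiment and ± 0.356 in the other.

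For 32 gene lists of tissue markers, hormone pathways, stress pathways and metabolism, 1 target per gene (the one of highest mean) was tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the 32 lists of each comparison. Each list test was repeated with an estimated correlation (statmod 1.5.0) and with fry, which asks whether the genes of a list move on balance one way. In simulated data a list shifted by 0.25 log2 was called in 5 of 5 simulations for both experiments with the preset correlation. With an estimated correlation it was called in 5 of 5 for the 0.1 µM experiment and in 0 of 5 for the other. The simulated genes varied independently. The simulations therefore cannot show how often the preset correlation gives false calls where genes of a list move together. Splits of the 0.1 µM arrays that mix the compared groups also called lists, as given at the end. Intervals of list means come from a limma fit of each list's mean per array and were added after the data were seen. They are not adjusted over the 32 lists or the comparisons, so some exclude 0 by chance. Such an interval for a list not called is not a call.

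The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names cyp19a1b, esr1, esr2a, esrrga and esrrgb in every comparison with control. It also names the largest changes past the threshold and the called members of called lists, of which there were none, and takes further names from the 5 rises and 5 falls of smallest unadjusted p with a symbol, which are said not to pass. Members of called lists given as examples are those of smallest p and were chosen after their values were seen. Members of called lists were also adjusted over their list alone. The list was called from the same values, so a member that rose, fell or passed in this way is no separate evidence. None of these members passed over all targets.

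Alternatives were another threshold, a fit of only the compared groups, repeated quantile normalisation, median centring, leaving out the 25% dimmest targets, trend and robust moderation, array weights, the replicate number as a block, the other deposited value tables, and each array left out in turn. For the lists they were an estimated correlation, fry and the mean of all targets of a gene. For compounds compared with each other, the list alternatives were added after seeing the data. All splits of the 0.1 µM arrays of each comparison into groups of 3, the real split included, were also tested. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and plots.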

Results

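Whole zebrafish embryos were profiled after exposure to compounds that act on estrogen receptors or estrogen-related receptors: bisphenol A (BPA), a plasticiser; 17β-estradiol (E2), the natural estrogen; and GSK4716, an agonist of estrogen-related receptors. At 0.1 µM each compound and the solvent control had 3 arrays. At high concentration, 80 µM BPA, 15 µM E2 and their own control had 2 arrays each. The median intensity per array ran from 561 to 577 in the 0.1 µM experiment and from 529 to 544 at high concentration. The correlation across targets between arrays of a group ran from 0.9962 to 0.9974 in the 0.1 µM experiment and from 0.9859 to 0.9943 at high concentration. The median SD within a group was 0.085 to 0.089 log2 in the 0.1 µM groups, 0.098 in the high-concentration controls, 0.144 at 80 µM BPA and 0.095 at 15 µM E2. All values below are log2 differences in intensity.

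BPA at 0.1 µM against control asked what a low concentration of the plasticiser changes in the embryo. Erythroid genes, which make haemoglobin and red cells, were slightly higher as a group: 16 of 19 members were higher, with a median of 0.07 (adjusted p = 9.2e-04). The call was not kept with an estimated correlation (adjusted p = 0.437 with an estimated correlation). Examples are cahz, a red cell carbonic anhydrase, at 0.18 (SE 0.07, n = 3 per group), tal1, a blood cell transcription factor, at 0.20 (SE 0.09) and the globin gene hbbe1.1 at 0.12 (SE 0.05). Genes of the yolk syncytial layer and liver, which secrete plasma proteins and lipoproteins, were also higher, 25 of 29 members with a median of 0.05 (adjusted p = 0.0019; adjusted p = 0.266 with an estimated correlation). Among them were rbp4l, a retinol carrier, at 0.23 (SE 0.08), ambp at 0.13 (SE 0.05) and mttp, which loads lipoproteins with lipid, at 0.16 (SE 0.07). Ribosomal protein genes were higher by a median of 0.02, 35 of 43 members (adjusted p = 0.024; adjusted p = 0.813 with an estimated correlation). The list means had 95% intervals of 0.01 to 0.17 for erythroid, 0.01 to 0.10 for yolk and liver and -0.03 to 0.08 for ribosomal protein genes, the last including 0. Aryl hydrocarbon and drug-metabolising cytochrome genes were not called (adjusted p = 0.2). Their list mean was 0.08 (95% interval 0.02 to 0.14, not adjusted over the lists). In each of the 3 lists, 0 members passed when adjusted over the list alone.

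No single target passed for 0.1 µM BPA: limma called 0 targets, with 2200 at an unadjusted p under 0.05 against 1924 expected by chance, and a smallest adjusted p of 0.534. The lower targets of smallest unadjusted p, which do not pass, were LOC566460 at -0.52 (SE 0.07), bnip3, a hypoxia-inducible gene of mitochondrial turnover, at -0.38 (SE 0.06), the small heat shock gene hspb3 at -0.39 (SE 0.06), hgfa, a growth factor, at -0.29 (SE 0.05) and trim35-29 at -0.37 (SE 0.06). The corresponding higher targets were si:dkey-158e13.3 at 0.44 (SE 0.08), adora3a.1, an adenosine receptor gene, at 0.73 (SE 0.15), LOC562362 at 0.62 (SE 0.13), LOC100001535 at 0.67 (SE 0.14) and arl5c at 0.28 (SE 0.06). The estrogen receptor gene esr1 (chromosome 20, 22984049 to 23007668) was at -0.22 (SE 0.07, adjusted p = 0.864). The brain aromatase gene cyp19a1b (chromosome 25, 1424055 to 1437720) was at -0.04 (SE 0.16), the second estrogen receptor gene esr2a at 0.03 (SE 0.11), and the estrogen-related receptor genes esrrga and esrrgb at 0.02 (SE 0.05) and -0.05 (SE 0.10). The erythroid call ended without control replicate 2 (adjusted p = 0.134), the yolk and liver call without control replicate 1 (0.0633) or BPA replicate 1 (0.0908), and the ribosomal call without control replicate 2 (0.495), BPA replicate 1 (0.561) or BPA replicate 3 (0.104), and with quantile normalisation repeated (0.221). BPA and control arrays did not overlap in 10.7% of targets, and chance gives 10%.

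E2 at 0.1 µM against control asked the same of the natural estrogen. Yolk syncytial layer and liver genes were higher, 23 of 29 members with a median of 0.10 (adjusted p = 3.67e-04; adjusted p = 0.132 with an estimated correlation; adjusted p = 0.018 by fry). Of these, 3 rose when adjusted over the list alone: the fibrinogen gene fgg by 0.24 (SE 0.06; chromosome 1, 17058130 to 17067714), the plasma protein gene itih2 by 0.18 (SE 0.05; chromosome 4, 17226719 to 17254775) and leg1.1, a secreted liver protein gene, by 0.29 (SE 0.08). Eye and lens genes were lower, 26 of 36 members with a median of -0.06 (adjusted p = 7.62e-04; adjusted p = 0.405 with an estimated correlation), among them the crystallin gene crygn2 at -0.28 (SE 0.08) and vsx1, a retinal transcription factor, at -0.17 (SE 0.06). Genes of neurons and neural progenitors were lower, 36 of 51 with a median of -0.04 (adjusted p = 0.0024; adjusted p = 0.405 with an estimated correlation); the proneural gene neurog1 was at -0.20 (SE 0.08). Circadian clock genes were higher, 19 of 26 with a median of 0.10 (adjusted p = 0.013; adjusted p = 0.608 with an estimated correlation), with hlfa at 0.18 (SE 0.07) and per2, a light-responsive clock gene, at 0.82 (SE 0.35). In the last 3 lists 0 members passed when adjusted over the list alone. The control arrays themselves stood apart in the clock list, with means relative to the control mean of -0.113, -0.102 and 0.215, against 0.109, 0.126 and 0.231 in the E2 arrays. The light-responsive gene cry1a, chosen after its values were seen, was at 9.62, 9.50 and 11.1 in the controls and 10.8, 10.7 and 10.8 with E2. The labels give neither the time of day nor the light at collection, which limits what the clock values show. The 95% intervals of the list means were 0.04 to 0.14 for yolk and liver, -0.13 to -0.01 for eye and lens, -0.08 to 0.00 for neural and 0.00 to 0.31 for clock genes. Genes of p53 and apoptosis, not called (adjusted p = 0.311), had a list mean of 0.06 (0.01 to 0.12).

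Estrogen-responsive genes were not called for 0.1 µM E2: 9 of 12 were higher, with a median of 0.08 (adjusted p = 0.204) and a list mean of 0.16 (95% interval 0.02 to 0.30), which was 0.10 without control replicate 1. limma called 0 targets, with 2587 at an unadjusted p under 0.05 and a smallest adjusted p of 0.708. The higher targets of smallest unadjusted p, which do not pass, were serpinc1, the antithrombin gene, at 0.29 (SE 0.05), or42b2 at 0.50 (SE 0.09), ckmt1, a mitochondrial creatine kinase gene, at 0.28 (SE 0.05), hcrt, the hypocretin neuropeptide gene, at 0.49 (SE 0.09), and si:ch211-224h1.4 at 1.03 (SE 0.20). The lower targets were LOC566460 at -0.42 (SE 0.07), zgc:123295 at -0.44 (SE 0.07), si:busm1-104n07.4 at -0.65 (SE 0.12), FER1L6 at -0.33 (SE 0.06) and trim35-29 at -0.34 (SE 0.06). cyp19a1b was at -0.05 (SE 0.16), esr1 at -0.03 (SE 0.07), esr2a at 0.02 (SE 0.11), esrrga at 0.00 (SE 0.05) and esrrgb at 0.09 (SE 0.10). Without control replicate 1 the eye and lens (adjusted p = 0.109), neuron (0.0542) and clock (0.221) calls ended, and the clock call also ended without control replicate 2 (0.386), without E2 replicate 3 (0.239) and with dim targets left out. The groups did not overlap in 12.1% of targets, where chance gives 10%.

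GSK4716 at 0.1 µM against control asked what exposure to an agonist of estrogen-related receptors changes. The lists called, all lower, were those of the eye, of neurons and of skeletal muscle. Eye and lens genes were lower in 29 of 36 members, with a median of -0.13 (adjusted p = 4.62e-06; adjusted p = 0.297 with an estimated correlation; adjusted p = 0.040 by fry). Of these, 5 fell when adjusted over the list alone: the lens membrane gene lim2.4 at -0.41 (SE 0.10; chromosome 19, 6187697 to 6200277), the eye transcription factor gene six6b at -0.31 (SE 0.08), the crystallin gene crygmx at -0.42 (SE 0.11), and the lens water channel genes mipb at -0.33 (SE 0.09) and mipa at -0.34 (SE 0.10). Neural genes were lower in 43 of 51 members, with a median of -0.09 (adjusted p = 1.98e-06; adjusted p = 0.173 with an estimated correlation; adjusted p = 0.011 by fry); 0 passed when adjusted over the list alone, with the proneural genes neurog1 and ascl1b at -0.31 (SE 0.08) and -0.27 (SE 0.07). Skeletal muscle genes were lower in 33 of 49 members, with a median of -0.07 (adjusted p = 4.33e-05; adjusted p = 0.336 with an estimated correlation; adjusted p = 0.040 by fry). In this list 8 members fell when adjusted over the list alone, among them the calcium pump gene atp2a1l at -0.61 (SE 0.10; chromosome 12, 12048757 to 12062568), the parvalbumin gene pvalb4 at -0.35 (SE 0.07), the myosin-binding gene mybpc2b at -0.26 (SE 0.06) and casq1a, a calcium store gene, at -0.22 (SE 0.05). Intervals (95%) of the list means were -0.20 to -0.07 for eye and lens, -0.13 to -0.05 for neural and -0.14 to -0.03 for muscle genes.

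Oxidative metabolism genes, which estrogen-related receptors are known to drive, did not pass with GSK4716: 24 of 30 were lower, with a median of -0.04 (adjusted p = 0.052). Hypoxia and glycolysis genes and pigment cell genes had medians of -0.07 and -0.06 and the same adjusted p of 0.052. Heart and notochord genes were not called either (adjusted p = 0.455 for both, medians of -0.01 and -0.05), but their list means were -0.07 (95% interval -0.11 to -0.03) and -0.06 (-0.10 to -0.01). Those of hypoxia and glycolysis and of oxidative metabolism genes were -0.09 (-0.14 to -0.04) and -0.06 (-0.11 to -0.01). The heart arrays were at -0.075, -0.073 and -0.067 with GSK4716 and 0.041, -0.017 and -0.024 in the controls. By fry the heart (adjusted p = 0.040) and hypoxia (0.045) lists passed. The thyroid hormone axis, not called, had a list mean of 0.08 (0.02 to 0.15). limma called 0 targets, with 3452 at an unadjusted p under 0.05 and a smallest adjusted p of 0.287. The lower targets of smallest unadjusted p, which do not pass over all targets, were hspb3 at -0.49 (SE 0.06), gprc6a at -0.43 (SE 0.06), the kinase gene sgk2b at -0.30 (SE 0.05), the mitochondrial ADP/ATP carrier gene slc25a4 at -0.38 (SE 0.06) and atp2a1l. The higher targets were LOC563925 at 0.85 (SE 0.14), zgc:153118 at 0.41 (SE 0.07), pmvk, a gene of cholesterol synthesis, at 0.32 (SE 0.06), LOC561644 at 0.60 (SE 0.11) and LOC570115 at 0.58 (SE 0.11). Values of cyp19a1b, esr1 and esr2a were 0.24 (SE 0.16), -0.07 (SE 0.07) and -0.04 (SE 0.11), and those of esrrga and esrrgb were -0.02 (SE 0.05) and 0.01 (SE 0.10). The groups did not overlap in 14.2% of targets, where chance gives 10%.

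**Figure D1:**
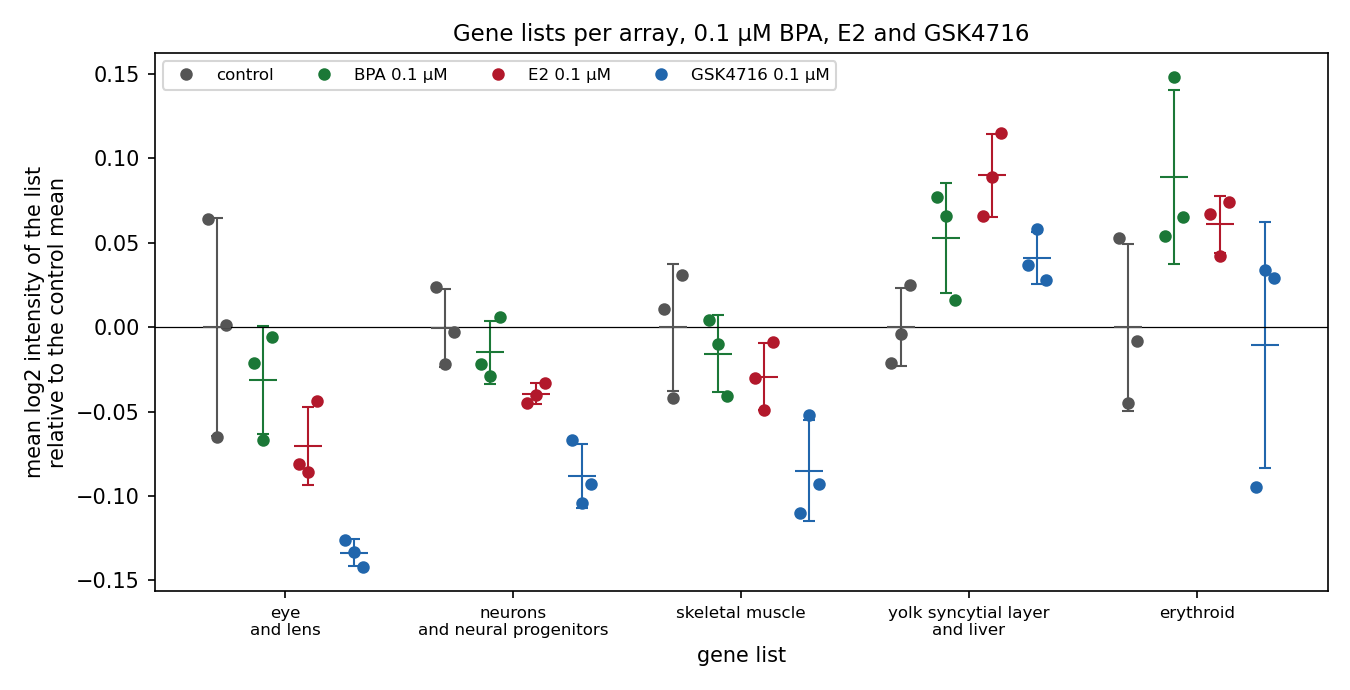
Mean log2 intensity of 5 gene lists on each array of the 0.1 µM experiment, relative to the control mean, by group; points are arrays, horizontal marks are group means and bars are 1 SD (3 arrays per group). The GSK4716 arrays lie below all control arrays in the eye and lens, neuron and skeletal muscle lists, with mean differences of -0.13, -0.09 and -0.09.

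BPA was then compared with the other compounds at the same 0.1 µM. Against E2, clock genes were lower with BPA, 23 of 26 with a median of -0.12 (adjusted p = 0.0144; adjusted p = 0.579 with an estimated correlation) and a list mean of -0.15 (95% interval -0.30 to 0.00). Within the BPA group cry1a was at 10.9, 10.8 and 9.87, so it split the arrays in a way that does not follow the groups, and the limit of unstated time and light at collection holds here too. Eye and lens genes were higher with BPA than with E2 by a median of 0.04 (adjusted p = 0.0144; adjusted p = 0.521 with an estimated correlation), neural genes by 0.01 (adjusted p = 0.0233; adjusted p = 0.521 with an estimated correlation) and ribosomal protein genes by 0.01 (adjusted p = 0.0423; adjusted p = 0.703 with an estimated correlation). The eye photopigment gene opn1sw1 was at 0.51 (SE 0.14), at a low mean log2 intensity of 4.81 with BPA, and the neural repressor gene her9 at 0.20 (SE 0.06). When adjusted over the list alone, 0 members of these 4 lists passed. The 95% intervals of the list means were -0.02 to 0.10, -0.02 to 0.06 and -0.03 to 0.07. Estrogen-responsive genes were not called, with 10 of 12 lower with BPA than with E2 (adjusted p = 0.0667) and a list mean of -0.26 (95% interval -0.40 to -0.12). Other lists not called had means of -0.11 (-0.19 to -0.02) for estrogen and estrogen-related receptors, -0.09 (-0.15 to -0.03) for p53 and apoptosis and -0.07 (-0.13 to -0.02) for immediate early genes. limma called 0 targets, with 2318 at an unadjusted p under 0.05. The smallest unadjusted p-values belonged to dnal4b at 0.36 (SE 0.07) and to cirbpb, a cold-inducible RNA-binding protein gene, at 0.24 (SE 0.05). On the lower side they belonged to si:dkey-287f10.1 at -0.33 (SE 0.05) and hmgb2, a chromatin protein gene, at -0.40 (SE 0.07). Without BPA replicate 1 the 4 calls ended, with adjusted p-values of 0.0756 (clock), 0.101 (eye and lens), 0.0902 (neural) and 0.349 (ribosomal), and without BPA replicate 3 they were 0.063, 0.063, 0.067 and 0.063. Leaving out E2 replicate 1 ended the eye (0.0551) and neural (0.0734) calls, E2 replicate 2 the eye (0.139), neural (0.086) and ribosomal (0.519) calls, and E2 replicate 3 the clock call (0.130). With the mean of all targets of a gene the neural and ribosomal calls ended (0.0762 for both), with dim targets left out the clock (0.0703) and ribosomal (0.0575) calls, and with quantile normalisation repeated the ribosomal call (0.0961). Without BPA replicate 3, 1 target without a symbol, AA495170_R, passed at 0.73 (adjusted p = 0.035), against 0.57 with all arrays.

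Against GSK4716, BPA embryos had higher expression of eye, neural, muscle, erythroid and oxidative metabolism genes. Eye and lens genes were higher in 30 of 36 members by a median of 0.10 (adjusted p = 1.87e-04; adjusted p = 0.315 with an estimated correlation), and 2 were higher when adjusted over the list alone: six3a by 0.28 (SE 0.06) and opn1sw1 by 0.60 (SE 0.14). The opn1sw1 signal was low, at a mean log2 intensity of 4.81 with BPA and 4.21 with GSK4716, which limits what its change shows. Neural genes were higher in 38 of 51 members by a median of 0.06 (adjusted p = 8.01e-05; adjusted p = 0.315 with an estimated correlation). Here 3 passed when adjusted over the list alone: ascl1b at 0.35 (SE 0.07), ascl1a at 0.34 (SE 0.08) and neurog1 at 0.33 (SE 0.08). Skeletal muscle genes were higher in 37 of 49 by a median of 0.07 (adjusted p = 8.01e-05; adjusted p = 0.315 with an estimated correlation); mybpc2b and pgam2 passed when adjusted over the list alone, both at 0.26 (SE 0.06). Oxidative metabolism genes were higher in 26 of 30 by a median of 0.06 (adjusted p = 0.0011; adjusted p = 0.401 with an estimated correlation), with slc25a4 at 0.31 (SE 0.06) the 1 member that passed when adjusted over the list alone. Erythroid genes were higher in 16 of 19 by a median of 0.09 (adjusted p = 7.72e-04; adjusted p = 0.401 with an estimated correlation), with 0 members past the threshold when adjusted over the list alone; this call ended without GSK4716 replicate 1 (0.159). The 95% intervals of the list means ran from 0.04 to 0.16 for eye, 0.03 to 0.11 for neural, 0.02 to 0.12 for muscle and for oxidative metabolism, and 0.02 to 0.18 for erythroid genes. Heart genes, not called (adjusted p = 0.0875), had a list mean of 0.08 (0.03 to 0.12) and passed by fry (adjusted p = 0.024). limma called 0 targets, with 4158 at an unadjusted p under 0.05 and a smallest adjusted p of 0.138, shared by hmgb2 at -0.55 (SE 0.07), LOC566460 at -0.51 (SE 0.07) and the glycine transporter gene slc6a5 at -0.38 (SE 0.05). The higher target of smallest p was HES5 (1 of 4) at 0.28 (SE 0.05). Without BPA replicate 3 AA495170_R passed at 0.99 (adjusted p = 0.002), against 0.83 with all arrays.

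E2 embryos differed from GSK4716 embryos in oxidative metabolism genes, higher in 27 of 30 with a median of 0.08 (adjusted p = 0.0026; adjusted p = 0.507 with an estimated correlation), and in skeletal muscle genes, higher in 41 of 49 with a median of 0.06 (adjusted p = 0.0026; adjusted p = 0.507 with an estimated correlation). The fatty acid carrier enzyme gene cpt1b was at 0.24 (SE 0.07), slc25a4 at 0.21 (SE 0.06) and mybpc2b at 0.21 (SE 0.06); 0 members passed when adjusted over the list alone. The list means had 95% intervals of 0.03 to 0.13 and 0.00 to 0.11. Estrogen-responsive genes were not called (adjusted p = 0.449) but had a larger list mean of 0.18 (0.03 to 0.32). Further lists not called had means of 0.08 (0.02 to 0.13) for glucocorticoid and stress axis, 0.07 (0.01 to 0.12) for conjugation and oxidative stress, and 0.05 for cell cycle (0.02 to 0.09), heart (0.01 to 0.09) and neural genes (0.01 to 0.09). limma called 0 targets, with 2669 at an unadjusted p under 0.05. hspb3 at 0.35 (SE 0.06), rdh12, a retinol dehydrogenase gene, at 0.29 (SE 0.05), and fgg at 0.26 (SE 0.06) were among the higher targets of smallest p, and nitr6b at -0.57 (SE 0.08), spon2b at -0.46 (SE 0.07) and the urotensin gene uts2b at -0.39 (SE 0.07) among the lower ones. The oxidative call ended without E2 replicate 3 (0.233) or GSK4716 replicate 3 (0.109), and the muscle call without E2 replicate 3 (0.155) or GSK4716 replicate 1 (0.0906). The groups did not overlap in 12.5% of targets for BPA and E2, 17.4% for BPA and GSK4716 and 12.4% for E2 and GSK4716, where chance gives 10%.

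BPA at 80 µM against its control asked what a high concentration of the plasticiser changes. Cholesterol synthesis and uptake genes were higher in 19 of 20 members, with a median of 0.24 (adjusted p = 1.12e-12; adjusted p = 0.376 with an estimated correlation) and a list mean of 0.26 (95% interval 0.09 to 0.43). Of these, 3 rose when adjusted over the list alone: hmgcra, which encodes the rate-limiting enzyme of cholesterol synthesis, by 0.68 (SE 0.13, n = 2 per group; chromosome 5, 38017201 to 38038360), insig1, a sterol-sensing regulator, by 0.60 (SE 0.13; chromosome 7, 36534277 to 36539670), and srebf2, the transcription factor that drives these genes, by 0.48 (SE 0.11; chromosome 3, 60916005 to 60933082). The synthesis enzyme gene mvda was at 0.37 (SE 0.10). Pigment cell and neural crest genes were higher in 20 of 27 members by a median of 0.05 (adjusted p = 0.0397; adjusted p = 0.987 with an estimated correlation) and a list mean of 0.08 (95% interval -0.15 to 0.30, or -0.04 to 0.20 with the replicate number as a block, both including 0), with the purine synthesis gene gart at 0.27 (SE 0.09) and 0 members past the threshold when adjusted over the list alone. The pigment call ended without control replicate 2 or BPA replicate 1, with quantile normalisation repeated and with the mean of all targets of a gene. The pigment list mean was 0 without control replicate 2 and turned to -0.03 without BPA replicate 1. It was 0.15 without control replicate 1 and 0.19 without BPA replicate 2. Estrogen-responsive genes were not called at 80 µM BPA, with a list mean of 0.13 (95% interval -0.09 to 0.35). Their list mean ran from 0.02 to 0.24 when each array was left out in turn.

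Single targets did not pass at 80 µM BPA: limma called 0, with 1306 at an unadjusted p under 0.05 and a smallest adjusted p of 1. The higher targets of smallest unadjusted p were si:dkey-193c22.2 at 1.13 (SE 0.13), si:busm1-40g1.17 at 0.99 (SE 0.11), SPINK2 (1 of 2) at 0.90 (SE 0.11), adka, the adenosine kinase gene, at 1.05 (SE 0.13), and nuggc.3 at 0.85 (SE 0.12). Among the lower targets of smallest unadjusted p were trim35-31 at -0.88 (SE 0.12), LOC100001003 at -0.81 (SE 0.12), si:ct573103.2 at -0.65 (SE 0.10) and LOC794116 at -0.73 (SE 0.12). cyp19a1b was at -0.33 (SE 0.21), or -0.03 without control replicate 1 and -0.62 without control replicate 2. The others were esr1 at 0.25 (SE 0.16), esr2a at 0.20 (SE 0.31), esrrga at -0.14 (SE 0.12) and esrrgb at 0.06 (SE 0.15). Without BPA replicate 2, 1 target without a symbol, CD605885_R, passed at 5.86 (adjusted p = 0.017), against 3.02 with all arrays. BPA and control arrays did not overlap in 27.4% of targets, where chance gives 33.3%.

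E2 at 15 µM against the same controls asked what a high concentration of estrogen changes. Cholesterol genes were again higher, in 18 of 20 members, with a median of 0.25 (adjusted p = 1.51e-06; adjusted p = 0.966 with an estimated correlation) and a list mean of 0.22 (95% interval 0.05 to 0.39). When adjusted over the list alone 1 member rose, hmgcra by 0.73 (SE 0.13), with srebf2 at 0.42 (SE 0.11) and sc5d, a late synthesis enzyme gene, at 0.49 (SE 0.13). Erythroid genes were higher in 19 of 19 members, with a median of 0.22 (adjusted p = 6.62e-07; adjusted p = 0.966 with an estimated correlation), including the transferrin receptor gene tfr1a at 0.49 (SE 0.16) and cahz at 0.44 (SE 0.17). White blood cell genes were higher in 11 of 15 by a median of 0.17 (adjusted p = 0.0425; adjusted p = 0.966 with an estimated correlation), with the macrophage receptor genes csf1ra at 0.67 (SE 0.14) and marco at 0.36 (SE 0.11). Skeletal muscle genes were lower in 39 of 49 by a median of -0.11 (adjusted p = 0.03; adjusted p = 0.966 with an estimated correlation), with myf5, a muscle progenitor transcription factor, at -0.58 (SE 0.11) and mybpc1, a slow muscle gene, at -0.70 (SE 0.17). The list means were 0.27 (95% interval 0.06 to 0.47) for erythroid, 0.18 (-0.02 to 0.38) for white blood cell and -0.09 (-0.31 to 0.12) for muscle genes, the last 2 with intervals that include 0. Whether the replicate numbers pair the arrays is not stated. With them as a block, added after the data were seen, the intervals were 0.05 to 0.30 for white blood cell and -0.21 to 0.03 for muscle genes. In the last 3 lists 0 members passed when adjusted over the list alone. Estrogen-responsive genes were not called at 15 µM E2, with a list mean of 0 (95% interval -0.22 to 0.22). Their list mean ran from -0.11 to 0.11 when each array was left out in turn.

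Among single targets at 15 µM E2, limma called 0, with 2438 at an unadjusted p under 0.05 and a smallest adjusted p of 0.632. The lower targets of smallest unadjusted p, which do not pass, included nkx2.2b, a transcription factor of the ventral neural tube, at -1.47 (SE 0.18; chromosome 20, 42511339 to 42515262). They also included si:ct573103.2 at -1.02 (SE 0.10), enpp7.1 at -1.13 (SE 0.12) and LOC100006322 at -0.79 (SE 0.10). The higher targets were adka at 1.14 (SE 0.13), pacsin3 at 0.95 (SE 0.11), si:dkey-193c22.2 at 0.96 (SE 0.13), tdo2b, a tryptophan-degrading enzyme gene, at 0.90 (SE 0.13), and nemp2 at 0.86 (SE 0.12). cyp19a1b was at -0.85 (SE 0.21, adjusted p = 0.667) at a low mean log2 intensity of 4.4 against 5.26 in controls, and at -0.56 without control replicate 1. esr1 was at 0.42 (SE 0.16, adjusted p = 0.774), esr2a at 0.08 (SE 0.31), esrrga at 0.04 (SE 0.12) and esrrgb at 0.22 (SE 0.15). The muscle call ended without control replicate 1 (list mean -0.02) or E2 replicate 2 (-0.03), and the list mean was -0.17 without control replicate 2. The white blood cell call ended without control replicate 2 (list mean 0.11) or E2 replicate 2 (0.2) and with dim targets left out. The white blood cell list mean was 0.25 without control replicate 1. Both calls ended with the mean of all targets of a gene. E2 and control arrays did not overlap in 40.4% of targets, where chance gives 33.3%.

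**Figure D2:**
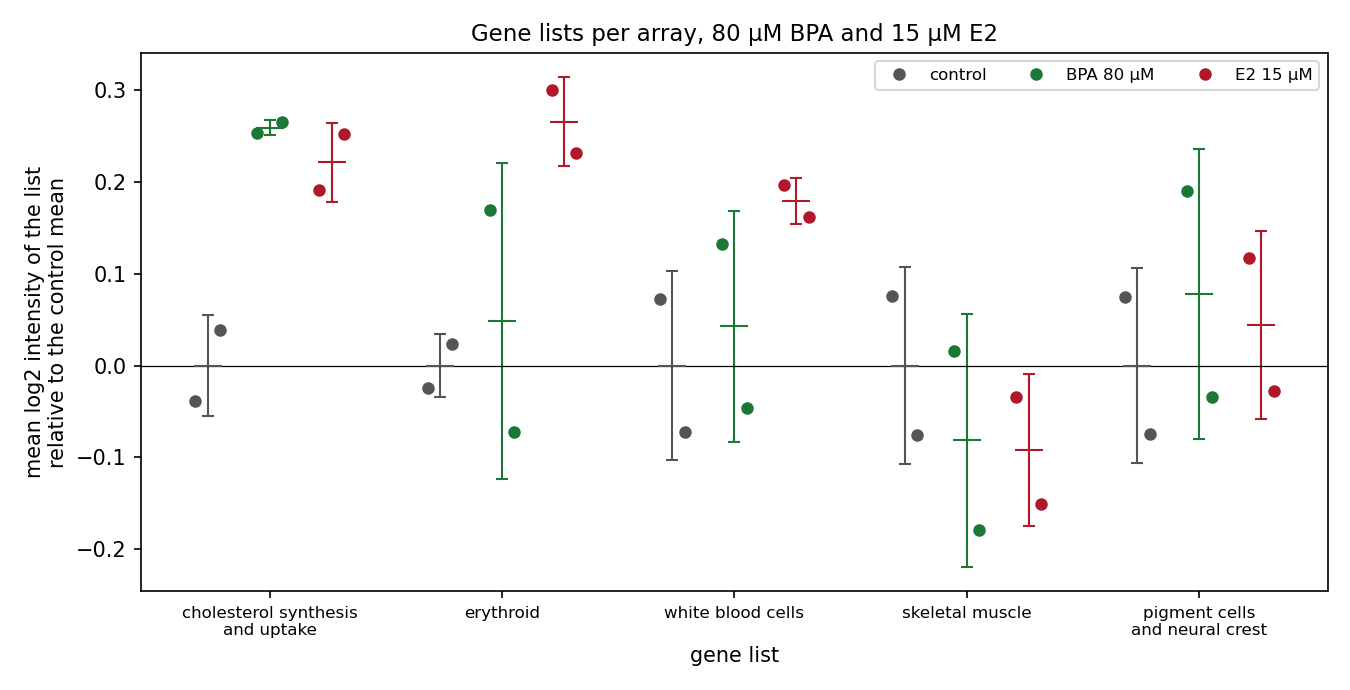
Mean log2 intensity of 5 gene lists on each array of the high-concentration experiment, relative to the control mean, by group; points are arrays, horizontal marks are group means and bars are 1 SD (2 arrays per group). The cholesterol list is at 0.254 and 0.265 in the BPA arrays and 0.191 and 0.252 in the E2 arrays, against -0.039 and 0.039 in the controls.

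BPA and E2 were compared directly at these concentrations, which differ (80 µM and 15 µM). Erythroid genes were lower with BPA than with E2 in 18 of 19 members, by a median of -0.16 (adjusted p = 2.03e-04; adjusted p = 0.895 with an estimated correlation) and a list mean of -0.22 (95% interval -0.43 to -0.01). Here 1 member, rfesd, was lower at -0.62 (SE 0.10) when adjusted over the list alone. The call ended without BPA replicate 2, where the list mean was -0.1. Without BPA replicate 1 the list mean was -0.34. Cholesterol genes did not differ past the threshold, with a median of 0.00 and 10 of 20 members higher (adjusted p = 0.410). limma called 0 targets, with 1474 at an unadjusted p under 0.05. Among the smallest p-values with a symbol were those of nkx2.2b, 1.42 higher with BPA (SE 0.18), and on the lower side those of LOC100001003 at -0.81 (SE 0.12), rfesd, and the integrin gene itga6l at -0.73 (SE 0.12). With trend and robust moderation 3 targets passed (adjusted p = 0.043), among them the overlapping targets TC243403 and ZV700S00003893 on chromosome 17, and without BPA replicate 2 CD605885_R passed (0.021). The groups did not overlap in 29.3% of targets, where chance gives 33.3%.

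Across targets, the fold changes of 80 µM BPA and 15 µM E2 correlated at 0.629, beside 0.5 simulated for unchanged groups that share their controls; targets are not independent replicates. With a separate control array for each compound the correlation was 0.189 or 0.194. Of the targets at an unadjusted p under 0.05 and at least 1.5-fold, 63 were higher with both compounds (175 with BPA, 300 with E2) and 47 lower with both (114 and 547). Independent lists would share 1.36 and 1.62, a figure that ignores the shared controls. At 0.1 µM the correlation was 0.584 for BPA and E2 (0.5 simulated), 0.545 for E2 and GSK4716 (0.501) and 0.42 for BPA and GSK4716 (0.499), the last below its simulated value. Between the concentrations, which were separate experiments with different platform records, it was -0.107 for BPA and -0.116 for E2.

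**Figure D3:**
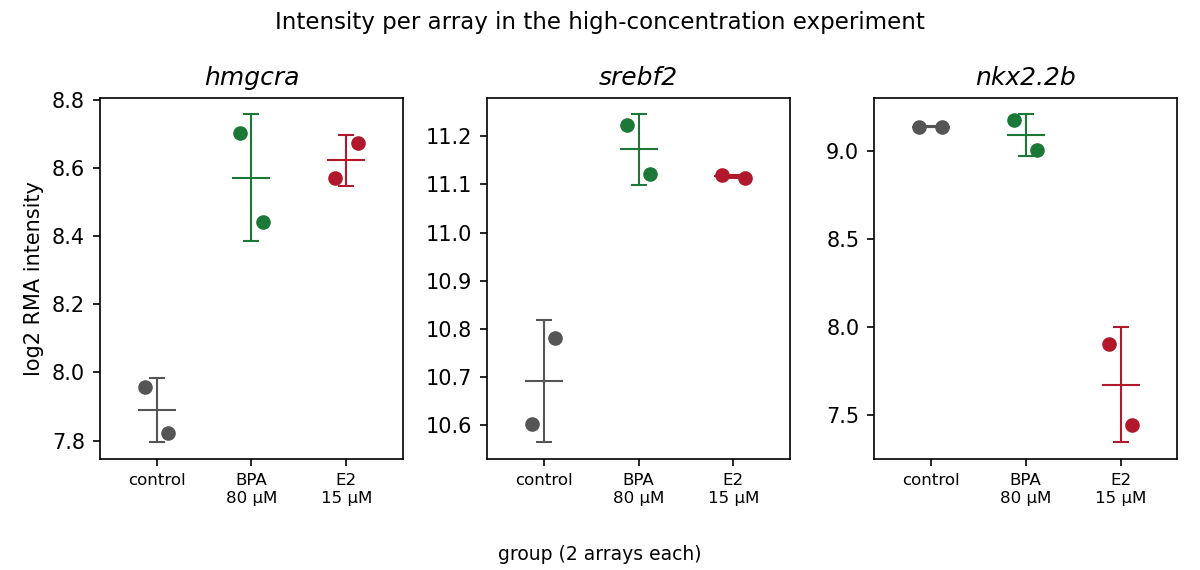
Log2 RMA intensity of hmgcra, srebf2 and nkx2.2b on each array of the high-concentration experiment, by group; points are arrays, horizontal marks are group means and bars are 1 SD (2 arrays per group). Both treatments lie above the controls for hmgcra and srebf2, and the E2 arrays lie below all other arrays for nkx2.2b.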

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

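The list alternatives for compounds compared with each other were added after the data were seen, as were the intervals of list means with the replicate block; the other alternatives were planned. Dim targets set a limit, since no detection calls are given. Apart from leave-one-out, counts of targets kept their side of the threshold in 80 comparisons and became larger in 10, and counts of lists stayed close in 29, became larger in 3 and smaller in 22. Requiring an unadjusted p and a 1.5-fold change gave 104 targets for BPA, 169 for E2 and 75 for GSK4716 at 0.1 µM, 289 for 80 µM BPA, 847 for 15 µM E2, and 47, 89, 77 and 351 for BPA against E2, BPA against GSK4716, E2 against GSK4716 and 80 µM BPA against 15 µM E2; this threshold is looser by construction. Trend and robust moderation gave 3 targets for 80 µM BPA against 15 µM E2, where the cause was not tested. With an estimated correlation 0 lists were called in all 9 comparisons. With fry, 0 were called for 0.1 µM BPA, 80 µM BPA, 15 µM E2, BPA against E2 at either concentration and E2 against GSK4716, 1 for 0.1 µM E2, 5 for GSK4716 and 2 for BPA against GSK4716. With the mean of all targets of a gene, 5 lists were called for GSK4716, 1 for 80 µM BPA, 2 for 15 µM E2 and 2 for BPA against E2 at 0.1 µM; with dim targets left out, 2 for BPA against E2 at 0.1 µM and 2 for 80 µM BPA against 15 µM E2; with quantile normalisation repeated, 1 for 80 µM BPA. The causes were not tested. With the replicate block, 0 targets passed in all 9 comparisons and all 28 called lists kept their call and direction. In the high-concentration experiment, deviations from the group mean correlated at 0.17 to 0.48 between arrays of the same number. With 2 arrays per group these deviations are equal and opposite, so both numbers give the same value. This is weak evidence that the numbers pair the arrays. Split controls moved the correlation of fold changes from 0.629 to 0.189 and 0.194. A shared control adds to this correlation, but the split also leaves each compound with a single, noisier control array. The 2 effects were not told apart.

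Leaving out each array in turn gave from 1 to 4 lists for BPA, 2 to 4 for E2 and 3 to 6 for GSK4716 at 0.1 µM, 1 to 9 for 80 µM BPA, 2 to 9 for 15 µM E2, 0 to 4 for BPA against E2, 0 to 3 for E2 against GSK4716 and 0 to 1 for 80 µM BPA against 15 µM E2. It gave 0 to 1 targets for 80 µM BPA, for BPA against E2 at either concentration and for BPA against GSK4716. Where a group keeps 1 array, that array is assumed to vary like the others. Fold changes near 0 changed sign without 1 array or another. For 0.1 µM BPA, cyp19a1b ran from -0.125 to 0.045, esr2a from -0.068 to 0.084, esrrga from -0.006 to 0.04 and esrrgb from -0.113 to 0.028. For 0.1 µM E2, cyp19a1b ran from -0.169 to 0.088, esr1 from -0.074 to 0.054, esr2a from -0.058 to 0.119 and esrrga from -0.027 to 0.022. For GSK4716, esr1 ran from -0.117 to 0.012, esr2a from -0.123 to 0.029, esrrga from -0.054 to 0.018 and esrrgb from -0.089 to 0.074. At 80 µM BPA, esr2a ran from -0.16 to 0.552 and esrrgb from -0.106 to 0.236; at 15 µM E2, esr2a ran from -0.198 to 0.358. Of the 5 genes named in every comparison with control, some kept their sign but moved by over 1.5 times. These were cyp19a1b at 80 µM BPA (-0.624 to -0.028), 15 µM E2 (-1.153 to -0.557) and GSK4716 (0.078 to 0.365), and esr1 at 0.1 µM BPA (-0.268 to -0.139) and 80 µM BPA (0.068 to 0.43). They were also esrrga at 80 µM BPA (-0.275 to -0.013) and 15 µM E2 (0.017 to 0.059), and esrrgb at 0.1 µM E2 (0.03 to 0.123) and 15 µM E2 (0.12 to 0.33). The other named genes kept their direction in the settings tried. Outside leave-one-out 1044 values kept direction and side, and 42 passed under the looser threshold or under trend and robust moderation. Only repeated quantile normalisation, median centring and array weights could have moved these fold changes. The other settings leave a difference of group means unchanged, so direction was fixed in advance there. The other deposited value tables hold the same values and could change nothing. Requiring a 1.5-fold change besides the adjusted p could not make a target pass. The side of the threshold was therefore fixed in advance in these settings, for named genes and for counts of targets.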

Other observations

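The tests of a single control array for the cholesterol genes, of a single E2 array, of an equal loss of neural cells, of younger embryos and of other splits for targets were chosen after the result was seen, as were vtg7, the clock genes and the idea of a Hedgehog list; the values of the Hedgehog members tested had not been seen when that list was written.

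vtg7, a vitellogenin gene and so a classic estrogen target, was at 0.70 with 0.1 µM E2 (SE 0.37, n = 3 per group, adjusted p = 0.753) and at -0.56 with 0.1 µM BPA (SE 0.37, adjusted p = 0.903) against control. Without control replicate 1 these were 0.29 and -0.98, and over all arrays left out in turn they ran from 0.29 to 0.96 and from -0.98 to -0.31. BPA minus E2 was -1.26 by limma (SE 0.37, adjusted p = 0.813, unadjusted p = 0.0063), and ran from -1.48 to -1.07 when each array was left out. The BPA arrays were at 8.03, 8.22 and 8.77, the E2 arrays at 9.56, 10 and 9.24, and the control arrays at 8.07, 9.22 and 9.41.

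The light-responsive clock gene cry1a had the largest spread within groups of the 5479 brighter genes of the 0.1 µM experiment, with a residual SD of 0.59 against a median of 0.086 over all genes. It was at 9.62, 9.50 and 11.1 in the controls, 10.9, 10.8 and 9.87 with BPA, 10.8, 10.7 and 10.8 with E2, and 10.7, 9.77 and 9.95 with GSK4716. The clock gene per2 was at 5.19, 5.50 and 6.74 in the controls, 6.48, 6.58 and 5.78 with BPA, 6.78, 6.54 and 6.55 with E2, and 6.37, 5.93 and 5.94 with GSK4716. The clock gene per1b ranked 4 in the same order. These values split the arrays in a way that does not follow the groups, and the labels give neither the time of day nor the light at collection.

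Cholesterol synthesis and uptake genes were higher with both 80 µM BPA and 15 µM E2, a call not kept with an estimated correlation (adjusted p = 0.376 and 0.966) or by fry (0.182 and 0.273). A single control array as the cause is argued against by the lowest median against 1 control array, 0.173. Background signal of dim targets is argued against by the brighter members, whose lower median was 0.185. A sterol response that raises synthesis and uptake but not efflux may account for it; this could not be tested, as 0 of the efflux genes abca1a, abca1b and abcg1 were measured under a name. A treatment effect thus stays open as a hypothesis, on 2 arrays per group.

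Targets of Hedgehog signalling were lower with 15 µM E2. The fall was not confined to the targets seen first: of the 17 members not seen first 16 were lower, with a median of -0.215. Of 10000 random lists of like expression 0% had a lower median, but these lists ignore that related genes move together. For the 17 members camera gave an unadjusted p = 1.63e-07 (p = 0.068 with an estimated correlation). Selection of extremes is not excluded, as these members were measured on the same E2 arrays as the targets seen first. A single E2 array is argued against by the unseen members' medians of -0.183 and -0.285 on the E2 arrays, against -0.045 to 0.097 on the other 4, though 9 of the 17 had both E2 arrays below the other 4. An equal loss of all neural cells is argued against by the unseen members' mean minus that of the neuron list without shared members, -0.24 (95% interval -0.38 to -0.11); a loss of ventral neural cells alone was not tested and stays open. Lower Hedgehog signalling with 15 µM E2 may account for it, a hypothesis found and tested on the same arrays; with 80 µM BPA the median was 0.023, and BPA minus E2 was 0.309 (p = 1.49e-12; p = 0.033 with an estimated correlation).

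Besides nkx2.2b, the targets seen first included TC243403 and ZV700S00003893 (-1.47 and -1.34), which overlap on chromosome 17 and carry the human counterpart NKX2-8 in the files. The unseen members included ptch1, a Hedgehog receptor gene, at -0.46 (SE 0.10), and the ventral neural tube genes nkx2.2a at -0.72 (SE 0.16), nkx6.2 at -0.46 (SE 0.10), foxa at -0.64 (SE 0.10) and tal2 at -0.47 (SE 0.13). In contrast pax9 was at 0.20 (SE 0.11). Other unseen members barely moved, with nkx6.1 at -0.08 (SE 0.19), prdm1a at -0.05 (SE 0.09) and en1b at -0.01 (SE 0.11). Over all targets 0 passed by limma. Of the 17, 5 were at an unadjusted p under 0.05, and these are the lower genes named here. Of the 17 members, 3 are also in the neuron list.

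Eye, neural and muscle genes were lower with GSK4716. A single array is argued against, as the 3 lists kept their call without each of the 6 arrays in turn (fewest called, 3), though not with an estimated correlation (adjusted p = 0.297, 0.173 and 0.336). Slightly younger embryos in the GSK4716 group might account for it: the segmentation and tailbud genes had a median of 0.012, with 13 of 24 higher and an upper quartile of 0.096, but a list mean of 0.06 (95% interval 0.00 to 0.11), with the GSK4716 arrays at 0.078, 0.033 and 0.056 against -0.011, 0.027 and -0.015 in the controls. The list was not called. Its mean leans toward the explanation but its median does not, so these values do not decide it. The GSK4716 arrays also have later sample numbers and titles of another form than the other 0.1 µM arrays. Whether they were handled separately is not stated, so a batch difference is possible in every comparison with GSK4716. Stage, such a batch and a direct effect cannot be told apart here, and chance is not excluded either. Other splits of the 6 arrays called up to 4 lists, against 3 for the real split.

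For each comparison in the 0.1 µM experiment, the 6 arrays make 10 splits, too few for a share under 0.05. For targets the real count was 0 in all 6 comparisons, so no split could give fewer and the splits test nothing. The highest other count was 2 for BPA, 0 for E2, 0 for GSK4716, 9 for BPA against E2, 3 for BPA against GSK4716 and 0 for E2 against GSK4716. For lists, with the real split counted among them, as many as the real number came from 2 splits for BPA (real 3, highest other 4), 2 for E2 (4 and 6) and 3 for GSK4716 (3 and 4). Between compounds, counted in the same way, this was 1 split, the real one itself, for BPA against E2 (4 and 2) and for BPA against GSK4716 (5 and 4), and 4 for E2 against GSK4716 (2 and 3). The fewest lists called by a split that mixes the groups were 1 for BPA, 1 for GSK4716 and 0 in the other comparisons. At the preset correlation, every mixed split for BPA and for GSK4716 thus called a list, so a call alone is weak evidence. What set the split with 9 targets apart was not tested.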
